A study of Mus musculus with 3 samples.

How the data were processed

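Forelimb buds were dissected from wild-type mouse embryos of 2 inbred strains, dissociated with trypsin and profiled by droplet single-cell RNA sequencing (10x Genomics 3′ chemistry, version 2), per the labels. Each droplet adds a cell barcode and each captured molecule a unique molecular identifier (UMI), so that copies made by PCR are counted once. The labels give 1 reaction per strain and stage: c57bl6.J at embryonic stage E9.5 (B6_E9.5), c57bl6.J at E10.5 (B6_E10.5) and 129S6.sv at E9.5 (129_E9.5). They set a target of up to 10000 cells for each library, which B6_E9.5 (12773 cells), 129_E9.5 (12220) and most of all B6_E10.5 (18957) exceeded; more cells in a reaction bring more doublets. The 3′ reads cover transcript ends, so that isoforms were not separated here.

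The values used were the raw UMI counts per gene and cell that the authors deposited as 1 matrix for all 3 libraries, with no normalization, per the file headers. The submitters' processing notes name Cell Ranger 3 and the mouse genome build mm10; the annotation release is not given in the sources used here. A deposited table gives each cell's stage, strain and 1 of 5 cluster numbers set by the authors, and each cell was assigned to its library by stage and strain. How the authors clustered the cells is not given in the sources used here. The matrix held 15122 genes and 43950 cells. The deposited counts bore marks of earlier filters: cells had between 501 and 38723 UMIs, between 218 and 4999 genes and at most 10% mitochondrial UMIs, and 15101 of the genes are protein coding in GENCODE M21. Of the versioned gene identifiers, 14775 were found in that release, and 15119 genes were matched to a symbol by identifier without version. Maenli, the long noncoding RNA of the series' title, was not analysed here. Barcodes of 1728 cells also occurred in another library and were kept apart by library. No further filter on cells was applied. Results of some genes are not reported here.

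The total per library was 124388358 UMIs in 12773 cells for B6_E9.5, 119942504 UMIs in 18957 cells for B6_E10.5 and 93029510 UMIs in 12220 cells for 129_E9.5. Shares of cells carry exact Clopper-Pearson 95% intervals and CPM values exact Poisson intervals. Ratios of CPM carry an interval from the exact conditional binomial. A count of 0 was given a limit of 3 counts. All of these intervals and limits cover counting error only, not differences between embryos or reactions.

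The comparisons, gene lists, markers and alternatives were set before the data were examined, unless stated otherwise. The authors' clusters were named from fixed marker lists among the 10 genes of highest fold in each cluster: limb mesenchyme, ectoderm (surface ectoderm plus apical ectodermal ridge), muscle progenitor, endothelium and myeloid, and erythroid. The myeloid part of that name is an exception. Markers of macrophages and other myeloid cells numbered 0 among these 10 genes and 5 among the 50 of highest fold. Further marker lists covered macrophages and other myeloid cells, megakaryocytes, neural crest and Schwann precursors, neurons and neural tube, somite and sclerotome, mesothelium and flank lateral plate, visceral endoderm and liver, and cardiomyocytes. Marker members without a row of that symbol (Sox1, Nkx3-2, Afp, Ttr, Alb and Nkx2-5) were not used here.

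For stage (B6_E10.5 over B6_E9.5) and strain (129_E9.5 over B6_E9.5), raw UMIs were summed over the limb mesenchyme and over the ectoderm of each library and divided by the class total to give CPM values. With 1 library in each group no test was possible, and genes were counted by size: a CPM ratio of at least 2 among genes with at least 50 CPM and 20 UMIs in the higher library. A ratio against a count of 0 was computed at 3 UMIs. The genes named were fixed by rule: the 12 largest and 12 smallest ratios among those genes whose interval excluded 1, with ribosomal, mitochondrial and uncharacterised Gm or Rik genes counted but not spelled out. The rule added up to 4 members with most UMIs of each gene list that stood apart, and always En1, Wnt7a, Lmx1b, Fgf8, Shh, Hoxd13, Hoxa13 and Tbx5.

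Gene lists covered dorsoventral limb patterning, 5′ Hox genes, 3′ Hox genes, Hedgehog signalling and posterior limb, FGF signalling and feedback, WNT signalling, BMP signalling, retinoic acid and proximal limb, limb bud transcription factors, chondrogenesis and skeletal condensation, connective tissue and matrix, and epithelial keratins and junctions. They also covered S phase, G2 and M phase, glycolysis and hypoxia, dissociation and heat stress, oncofetal and imprinted growth genes, haemoglobin genes, mitochondrial transcripts, Y-linked genes and housekeeping genes. The Y-linked list was set as a measure of the mix of embryo sexes in a library. The median log2 ratio of each list's members with at least 20 UMIs in the pair was set against 10000 random lists of the same size matched on mean expression in 50 bins. A list was said to stand apart under percentile 2.5 or over percentile 97.5, as a description of these libraries. In ectoderm the medians were also taken, as an alternative added after the data were seen, over genes above 20% of their mesenchymal level in the library with the higher ectodermal level, with random lists drawn from such genes. List members without a row of that symbol (Acan, Matn1, H19, Meg3, Xist and Tsix) were not used here.

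En1 was counted per class and library, and its co-occurrence with Wnt7a, Fgf8 and Lmx1b in ectodermal cells was given as an odds ratio with an exact interval. Shares of cells were computed again after thinning each cell to 2000 UMIs, leaving out shallower cells. For the En1 test, ectodermal cells with at least 1 En1 UMI and those with none were summed per library, giving 3 pairs of sums. The sums were compared with edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit and glmQLFTest, 2-sided) with the library as a block and 2 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p of 0.05, and En1 itself was left out because it defined the classes. The pairing comes from the design, since both sums of a pair are cells of the same library. The 3 libraries are of 3 conditions, so the test asks what held over all of them. Its p-values rest on how the difference between both sums of a pair varied over these libraries, which may be technical. In edgeR this spread is moderated over all genes. Up to 15 genes of smallest adjusted p in each direction were named.

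An own clustering, used as an alternative and to look for smaller cell types, took log-normalised counts (scaled to 10000 per cell), 2000 variable genes, 30 principal components, 15 neighbours and Leiden at resolution 1, and gave 26 clusters. A cluster was named where at least 3 markers of a list reached 25% of their highest cluster mean. Scrublet (in scanpy 1.11.5) marked 0.164%, 0.00528% and 0.147% of the cells of B6_E9.5, B6_E10.5 and 129_E9.5, too few to count as a working doublet call, and doublets were kept. Removing the 8% of cells of highest doublet score in each library was added after the data were seen.

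The ratio counts were tested on simulated data drawn from the real means and library sizes, with 100 genes changed 4-fold. Of these, 100 were recovered for stage in mesenchyme, 99 for strain in mesenchyme, 99 for stage in ectoderm and 100 for strain in ectoderm, and 0 unchanged genes were called among the 2983, 2967, 3040 and 3066 genes tested. These draws held counting error only. They say nothing about 2-fold calls that come from differences between embryos or reactions. In simulated En1 sums of 10608 genes, edgeR recovered 91 of 100 genes changed 2-fold and 97 of 100 changed 4-fold, and 5 unchanged genes passed. Every gene was drawn with the same dispersion (0.00426), estimated from the real sums. These draws therefore do not show how the test does where the spread differs between genes or libraries.

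Alternatives were TMM factors or totals without haemoglobin, mitochondrial and ribosomal protein genes for scaling, no CPM filter, cells with at most 5% mitochondrial UMIs and at least 2000 genes, Scrublet calls removed, thinned cells, the own clustering, shares of non-erythroid cells and list members with at least 100 UMIs. For the En1 test they were DESeq2 1.42.0, RLE factors, no filter beyond 1 UMI, no library block, thinned cells, no cells with an Fgf8 UMI, En1-positive Wnt7a-negative against Wnt7a-positive En1-negative cells, and each library left out in turn. Restriction to cells of at least 2000 UMIs and 129_E9.5 as the earlier library were added after the data were seen. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.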

Results

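Single-cell transcriptomes were collected from the forelimb buds of wild-type mouse embryos as 3 libraries, 1 per group: B6_E9.5 and B6_E10.5 from the strain c57bl6.J at embryonic stages E9.5 and E10.5, and 129_E9.5 from the strain 129S6.sv at E9.5. At these stages the bud is a pocket of mesenchyme covered by ectoderm, and the engrailed-1 gene (En1) of the series' title marks ectoderm of the ventral side. The libraries held 124388358 UMIs in 12773 cells (B6_E9.5), 119942504 UMIs in 18957 cells (B6_E10.5) and 93029510 UMIs in 12220 cells (129_E9.5). There were no replicates, so differences between stages or strains have no replicate check and no test, and their intervals cover counting error only. Depth per cell differed: the median was 7623 UMIs in B6_E9.5, 5710 in B6_E10.5 and 7348 in 129_E9.5. Cells under 2000 UMIs made up 30.8% of B6_E9.5, 10.1% of B6_E10.5 and 3.49% of 129_E9.5, and cells of at least 16000 UMIs 29.8%, 2.38% and 2.66%.

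The authors' 5 clusters carried the markers of limb mesenchyme (leading genes Shox2, Prrx1 and Tbx5), ectoderm (Fgf8, Wnt6 and Epcam), muscle progenitors (Pax3, Lbx1 and Eya1), endothelium and myeloid cells (Emcn, Cldn5 and Pf4) and erythroid cells (Hba-x, Hba-a1 and Alas2). Pf4 belongs to the megakaryocyte list, and 0 markers of macrophages and other myeloid cells were among the 10 leading genes of its cluster. Limb mesenchyme was the main class, with 75.8% of the cells of B6_E9.5 (95% interval 75 to 76.5), 80.8% of B6_E10.5 (80.3 to 81.4) and 75.6% of 129_E9.5 (74.8 to 76.3). Muscle progenitors were 2.23% of B6_E9.5 (1.98 to 2.5), 7.90% of B6_E10.5 (7.52 to 8.30) and 5.29% of 129_E9.5 (4.90 to 5.71). Ectoderm was 7.90% of B6_E9.5 (7.44 to 8.38), 5.41% of B6_E10.5 (5.09 to 5.74) and 10.3% of 129_E9.5 (9.72 to 10.8). Endothelium and myeloid cells were 6.65%, 3.73% and 3.75% of the same libraries, and erythroid cells 7.45%, 2.12% and 5.15%. Shares are set by dissection and recovery as well as by the tissue, and the erythroid class of B6_E9.5 had a median of 735 UMIs per cell, with haemoglobin at 3.56% of UMIs, against 14608 UMIs and 52.4% in B6_E10.5 and 12004 UMIs and 52.8% in 129_E9.5. Among cells of at least 2000 UMIs, a limit set after the data were seen, the erythroid share of B6_E9.5 was 1.78% and its ectodermal share 10.03%, against 9.81% in 129_E9.5. With cells of at most 5% mitochondrial UMIs and at least 2000 genes the order of the E9.5 libraries turned for both classes, with ectoderm at 9.75% of B6_E9.5 and 6.67% of 129_E9.5 and erythroid cells at 1.61% and 2.93%.

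**Figure D1:**
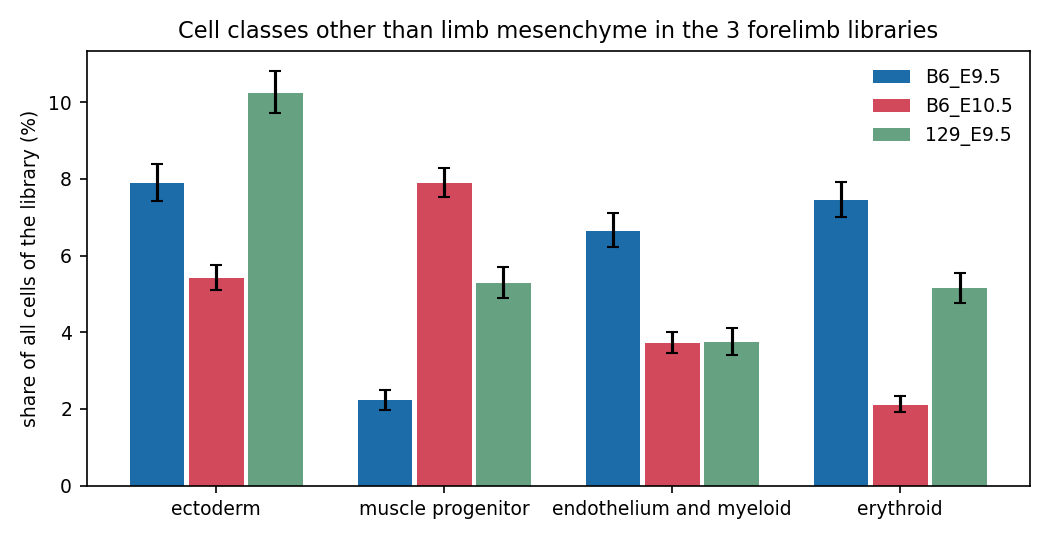
Share of all cells of each library in 4 of the 5 cell classes, in percent, as bars with exact 95% binomial intervals (counting error only), for B6_E9.5, B6_E10.5 and 129_E9.5. Muscle progenitors stand at 2.23%, 7.90% and 5.29%, and limb mesenchyme, which is not drawn, holds 75.8%, 80.8% and 75.6%.

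Summed markers of each class were highest in their own class. In B6_E9.5, B6_E10.5 and 129_E9.5, limb mesenchyme markers reached 1901, 1980 and 1953 CPM in mesenchyme and 544, 373 and 451 CPM in ectoderm. Of the ectodermal values, the list member Msx1 made up 303, 111 and 222 CPM. Surface ectoderm markers reached 2745, 2459 and 3031 CPM in ectoderm and apical ectodermal ridge markers, whose signals drive outgrowth of the bud, 1804, 1769.6 and 1478 CPM. Muscle progenitor markers stood at 1143, 1067 and 1057 CPM in the muscle class, endothelium markers at 4331, 3319.6 and 4618 CPM in the endothelial class, and erythroid markers at 319144, 506281 and 520074 CPM in the erythroid class. Erythroid markers were also found in mesenchyme, at 1330.2 CPM in B6_E9.5, 299 CPM in B6_E10.5 and 450.3 CPM in 129_E9.5. Somite and sclerotome markers in mesenchyme were at 17.0, 152 and 23.0 CPM, and those of mesothelium and flank lateral plate at 68.6, 160.04 and 61.3 CPM. Megakaryocyte markers in the endothelial class were at 224, 1359 and 276 CPM, and neural crest and Schwann precursor markers in the same class at 8.00, 157 and 121 CPM. Visceral endoderm and liver markers and cardiomyocyte markers were low in mesenchyme, at most 4.88 and 3.53 CPM, both in B6_E9.5.

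En1 was counted mainly in the ectodermal class. It was counted at 104.98 CPM (95% interval 98.9 to 111) in the ectoderm of B6_E9.5, 93.2 CPM (85.8 to 101) in B6_E10.5 and 101 CPM (93.6 to 109) in 129_E9.5, and at 1.47, 1.08 and 1.37 CPM in limb mesenchyme. The gene lies on chromosome 1 of mm10, from 120602418 to 120607992. At least 1 En1 UMI was found in 38.7% of the 1009 ectodermal cells of B6_E9.5 (35.6 to 41.7), 31.0% of the 1026 of B6_E10.5 (28.2 to 33.9) and 27.9% of the 1253 of 129_E9.5 (25.4 to 30.4). The median depths of these cells were 10410, 5731.5 and 4747 UMIs, and after thinning to 2000 UMIs in 887, 912 and 1157 cells the shares were 17.9%, 13.5% and 15.8%. As a background level, 1.24%, 0.574% and 0.953% of limb mesenchyme cells had an En1 UMI at median depths of 8067, 5422 and 7463 UMIs. The highest other class was the muscle class of B6_E9.5, at 2.11% of cells, and in the endothelial class of B6_E10.5 En1 was found in 0 of 707 cells, which allows a share of up to 0.424% of cells with a UMI and sets no limit on cells that express the gene.

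Other patterning genes differed in level between the libraries. Wnt7a, the dorsal ectodermal WNT ligand on chromosome 6 (91363981 to 91411363), was counted at 56.7 CPM in the ectoderm of B6_E9.5, 31.5 in B6_E10.5 and 66.4 in 129_E9.5. Fgf8, the apical ridge growth factor on chromosome 19 (45736798 to 45742915), was at 527, 1003 and 743 CPM in ectoderm. Lmx1b, the dorsal mesenchymal transcription factor on chromosome 2 (33560965 to 33640511), was at 61.9, 21.5 and 43.4 CPM in limb mesenchyme.

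**Figure D2:**
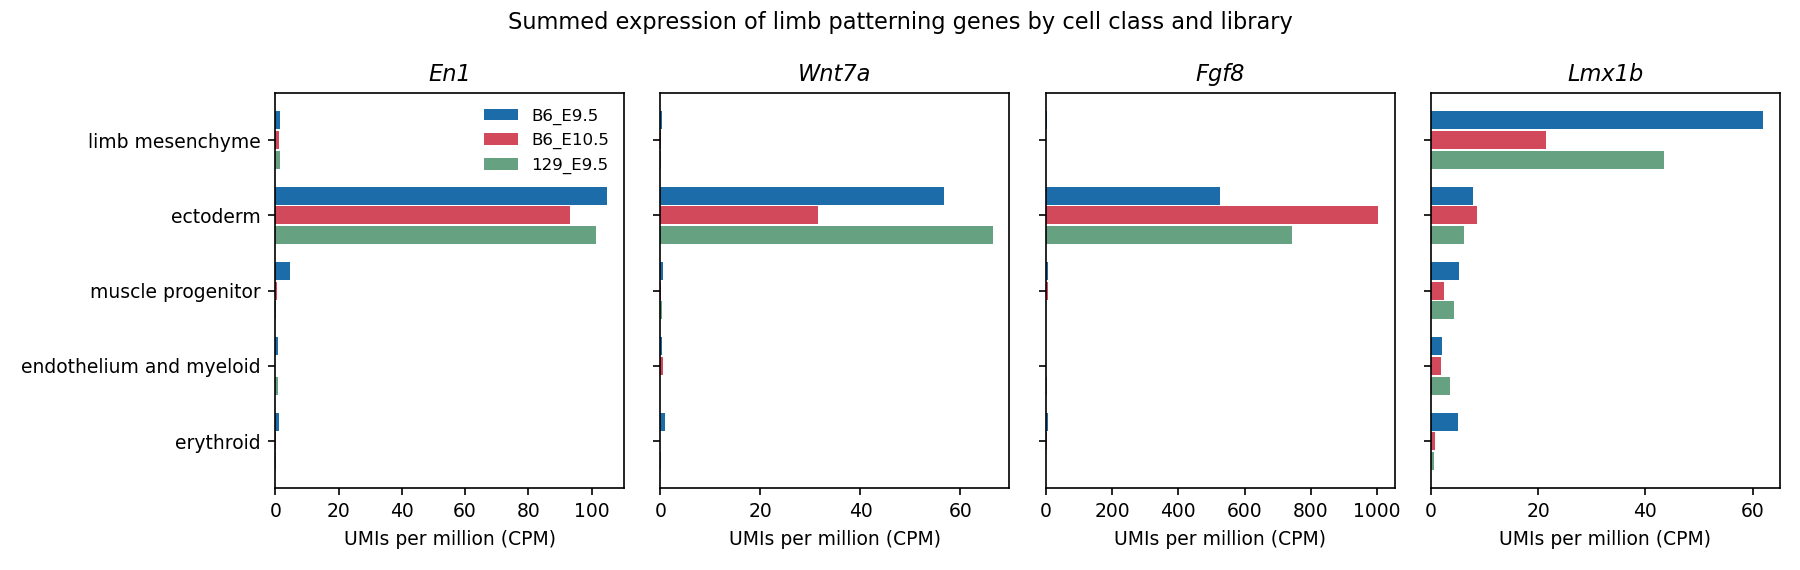
Expression (CPM) of En1, Wnt7a, Fgf8 and Lmx1b in the 5 cell classes, as bars from 0 for each of the 3 libraries, with a separate axis range for each gene. En1 stands at 104.98, 93.2 and 101 CPM in the ectoderm of B6_E9.5, B6_E10.5 and 129_E9.5, and Lmx1b at 61.9, 21.5 and 43.4 CPM in limb mesenchyme.

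En1 and Wnt7a, which mark opposite faces of the bud, were rarely counted in the same ectodermal cell. The odds ratio of having both was 0.0722 (95% interval 0.0390 to 0.125) in B6_E9.5, 0.0467 (0.00943 to 0.142) in B6_E10.5 and 0.0645 (0.0253 to 0.137) in 129_E9.5, with 15, 3 and 7 cells positive for both. Of the Wnt7a-positive cells 6.36%, 2.44% and 3.11% had an En1 UMI, against 48.5%, 34.9% and 33.3% of the Wnt7a-negative cells. En1 and Fgf8 had odds ratios of 0.907 (0.697 to 1.18), 1.69 (1.24 to 2.30) and 0.679 (0.520 to 0.883), and those of En1 and Lmx1b were 1.09, 0.820 and 1.36 with intervals that all included 1. After thinning, the odds ratio of En1 and Wnt7a was 0.0467 in B6_E9.5, 0 in B6_E10.5 and 0.0432 in 129_E9.5. That of En1 and Fgf8 in B6_E9.5 was then 0.524 (0.339 to 0.794), an interval that excluded 1 where the one before thinning included it. In B6_E10.5 and 129_E9.5 the thinned odds ratios of En1 and Fgf8 were 1.86 (1.20 to 2.84) and 0.598 (0.415 to 0.852).

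To ask which genes go with En1 in the ectoderm over all 3 libraries, cells with an En1 UMI were compared with those without (390 against 619 cells in B6_E9.5, 318 against 708 in B6_E10.5 and 349 against 904 in 129_E9.5). Genes that rose in En1-positive cells included Msx2, a BMP-responsive homeobox gene (log2 fold change 0.75, SE 0.067), the homeobox genes Dlx1 (0.90) and Dlx2 (0.70), the BMP pseudoreceptor Bambi (0.67), the WNT receptor Fzd1 (1.01) and the T-box gene Tbx3 (0.69). Wnt7a fell by the widest margin among the named genes (log2 fold change -4.37, SE 0.167). With it went the repulsive guidance gene Sema3a (-1.64), the phosphatase subunit Ppp2r2c (-3.60), the connexin gene Gjb2 (-1.93), the neurotrophin receptor Ngfr (-3.50), the basal keratin Krt14 (-0.87) and the WNT antagonist Sfrp1 (-1.16). Every gene named in this paragraph had the same direction in 3 of 3 libraries, which the choice by smallest p over these same libraries favours. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 71 of 10608 genes rose and 81 fell, with adjusted p = 2.44e-05 for Msx2, 7.18e-05 for Dlx1, 1.00e-04 for Fzd1, 3.18e-06 for Sema3a and 2.68e-10 for Wnt7a.

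The other genes of smallest adjusted p that rose were Sct, which encodes secretin (log2 fold change 0.63), Hoxc9 (0.79), Hoxc8 (0.55), the integrin gene Itga4 (1.00), the glutamate transporter gene Slc1a3 (0.73), Pxdc1 (1.06), Igfbp5, an insulin-like growth factor binding protein (0.54), the imprinted zinc-finger gene Zim1 (1.04) and Ccdc194 (1.28). The others that fell were the glutaredoxin gene Glrx (-1.42), the metallothionein gene Mt1 (-1.23), the transcription factor Batf3 (-1.76), Emb (-0.80), the serine protease gene Prss23 (-1.28), the imprinted gene Peg10 (-1.37), the growth-cone gene Gap43 (-1.38) and Tril (-1.43). All had the same direction in 3 of 3 libraries, which the same choice favours. Fgf8 did not pass (log2 fold change -0.21, adjusted p = 0.675 by edgeR), with values of -0.47 in B6_E9.5, 0.50 in B6_E10.5 and -0.69 in 129_E9.5. Lmx1b (-0.48, adjusted p = 0.552) and the forelimb gene Tbx5 (-0.40, adjusted p = 0.778) did not pass either.

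By fixed list, BMP signalling had 3 members that rose (Bambi, Id4 and Msx2) and 0 that fell of 13 tested, and 8 and 0 when adjusted over the list alone. Of 18 epithelial keratins and junctions 0 rose and 3 fell (Krt14, Krt17 and the surface ectoderm factor Tfap2a), and 0 and 6 adjusted over the list alone. Of 16 WNT genes 2 rose (Dkk1 and Wnt5a) and 1 fell (Wnt7a), and 4 and 3 adjusted over the list alone. Of 12 dorsoventral patterning genes 2 rose (Dkk1 and Msx2) and 1 fell (Wnt7a), and 4 and 2 adjusted over the list alone. Of 11 apical ridge markers 2 rose (Dlx2 and Msx2) and 0 fell, and 4 and 1 adjusted over the list alone, while of 15 surface ectoderm markers 0 rose and 2 fell, and 1 and 5 adjusted over the list alone. Members that passed elsewhere included Hoxc9 of the 5′ Hox genes, Hoxc8 (rose) and Hoxc4 (fell) of the 3′ Hox genes, Tbx3 (rose) and Gas1 (fell) of the Hedgehog list, Spry1 (rose) of the FGF list, Crabp2 (fell) of the retinoic acid list, Emx2 (fell) of the limb bud transcription factors, and Col1a2 (rose) of the matrix list. The glucose transporters Slc2a1 and Slc2a3 fell, as did Actb of the housekeeping list. Among oncofetal and imprinted genes Peg3 rose, and Dlk1 and Peg10 fell. Of the markers of other cell types, Col1a2 and Tbx3 of limb mesenchyme rose, and Tfap2b of neural crest and Meox1 of the somite fell. Neither Col1a2 nor Tbx3 was specific to mesenchyme. In the ectoderm of B6_E9.5, B6_E10.5 and 129_E9.5, Col1a2 stood at 298%, 38.1% and 225% of its mesenchymal level, and Tbx3 at 167%, 101% and 157%. In edgeR, 0 members passed in the chondrogenesis, S phase, G2 and M phase, stress, haemoglobin, mitochondrial and Y-linked lists, where adjustment over the list alone gave 3 that rose in chondrogenesis, 3 that fell in S phase, 1 that rose in G2 and M phase and 1 that rose in stress.

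**Figure D3:**
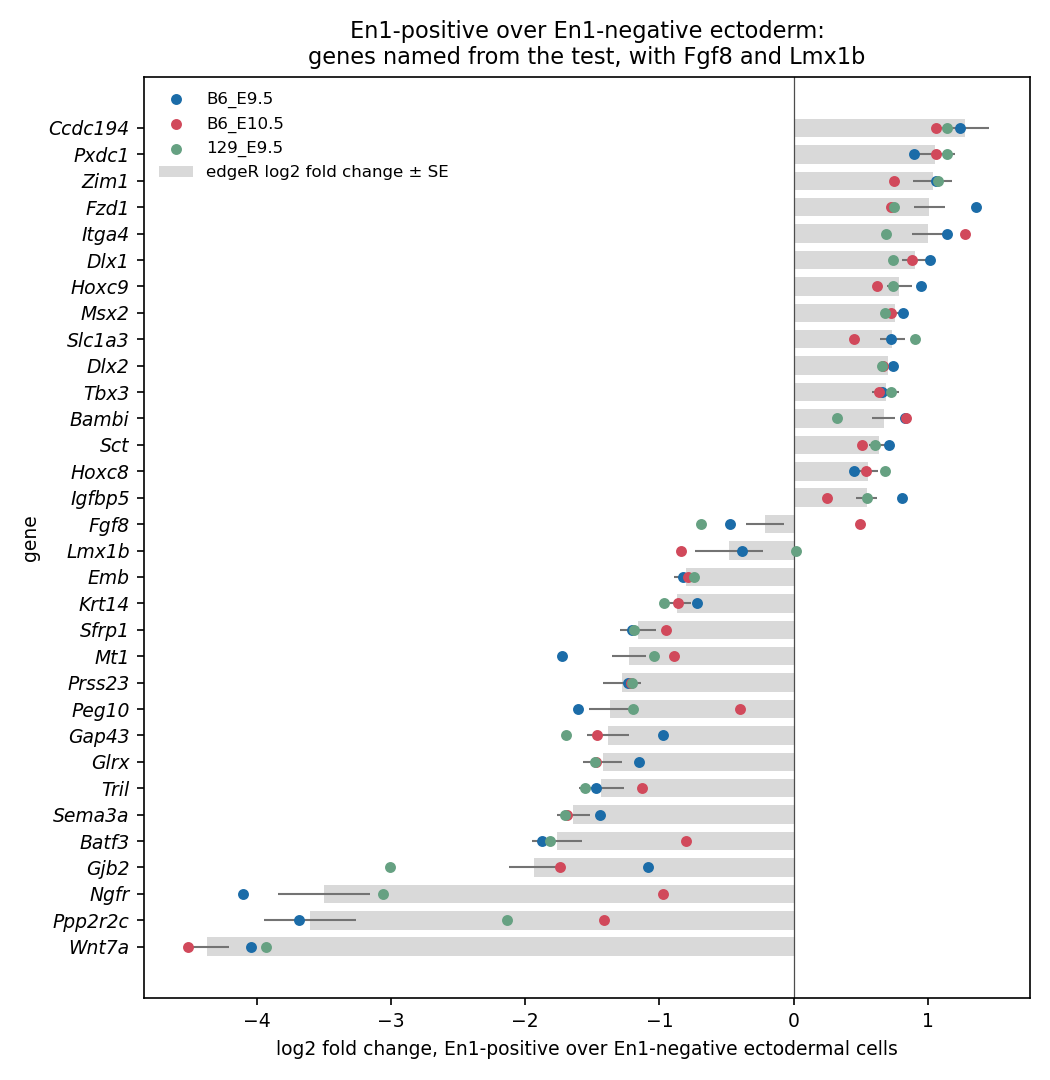
Log2 fold change of En1-positive over En1-negative ectodermal cells for the 30 named genes of the test plus Fgf8 and Lmx1b, with grey bars for the edgeR estimate ± SE and points for each of the 3 libraries. Wnt7a has the lowest fitted value of the genes drawn, -4.37, and Fgf8 has points on both sides of 0 (-0.47, 0.50 and -0.69).

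En1-positive cells were also deeper than En1-negative cells, with medians of 12572 against 8354 UMIs in B6_E9.5, 7002.5 against 5110 in B6_E10.5 and 5146 against 4554 in 129_E9.5, and with cells thinned to 2000 UMIs, which left 159, 123 and 183 En1-positive cells, 6 genes rose and 4 fell. The counts moved with single libraries: without B6_E9.5 8 rose and 26 fell, and without B6_E10.5 243 rose and 246 fell. DESeq2 gave 22 and 25, all among the genes called by edgeR.

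The stage comparison asked how the forelimb mesenchyme of c57bl6.J differed between E9.5 and E10.5. By their median log2 ratios, the chondrogenesis and 5′ Hox lists were higher at E10.5, and the 3′ Hox, WNT and glycolysis lists were lower. Scx, the tendon transcription factor, was at 80.6 CPM against 1.96, a ratio of 41.1 (95% interval 35.6 to 47.7), and the cartilage collagen genes Col2a1 and Col9a1 had ratios of 13.4 (12.1 to 14.7) and 12.1 (11.3 to 13.0). Cyp26b1, which degrades retinoic acid, was 18.3-fold higher (16.5 to 20.3) and Hoxd11 13.7-fold (12.9 to 14.6). Lin28a, which blocks maturation of let-7 microRNAs, was at 2.18 CPM against 84.4, which is 38.7-fold lower (33.6 to 44.8). Hoxb9, a member of the 5′ Hox list that went against its median, was 43.0-fold lower (36.7 to 50.8).

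The other largest ratios were those of Pmaip1, a pro-apoptotic BH3-only gene (109, interval 84.4 to 142), Mab21l2 (31.2), the transcription factor Osr2 (30.1), the Slit receptor Robo2 (25.1), the WNT potentiator Rspo3 (13.7), Itm2a (10.8) and Fibin (10.7). At the other end, the histone gene Hist1h2ap was 23.9-fold lower, Hoxb6 12.3-fold, the chromatin gene Hmga1 11.2-fold, Hoxb8 9.73-fold, Prtg 8.78-fold, Jaml 7.71-fold, the embryonic globin gene Hbb-bh1 7.16-fold, Alx1 5.43-fold, the WNT inhibitor Apcdd1 5.31-fold and Usp50 4.98-fold. In all, 151 genes were at least 2-fold higher and 88 at least 2-fold lower of 3303 tested. With TMM factors the counts were 118 and 132, and the median log2 ratio of all tested genes moved from -0.01 to -0.16.

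Among the fixed lists, 8 of 10 chondrogenesis genes were at least 2-fold higher and 0 lower (median log2 ratio 2.94), led by Sox9, the chondrogenic master regulator (10.6-fold, 10.1 to 11.1), and including Wwp2 (4.26-fold). Of 16 connective tissue and matrix genes 6 were higher and 1 lower (median 0.77), with Col1a2 7.46-fold, Tcf4 2.03-fold, Col3a1 1.71-fold and Fbn2 1.25-fold higher. The 22 3′ Hox genes had 0 higher and 18 lower (median -1.57), with Hoxa5 2.30-fold, Hoxc6 2.21-fold, Hoxd4 2.17-fold and Hoxa7 1.74-fold lower. The 11 5′ Hox genes had 6 higher and 3 lower (median 1.24): Hoxa10 was 3.09-fold and Hoxd13 4.38-fold higher (4.03 to 4.76), and Hoxa13 rested on 569 against 5 UMIs (ratio 124, 52.6 to 382). The 3 lower genes were Hoxd9 (2.35-fold lower), Hoxb9 (ratio 0.0232) and Hoxc9 (ratio 0.239). Short of 2-fold, Hoxa9 was 1.40-fold and Hoxd10 1.24-fold lower. Hoxd13 lies on chromosome 2 (74668310 to 74671599) and Hoxa13 on chromosome 6 (52257694 to 52260880). Hedgehog and posterior genes had 6 higher and 0 lower of 15 (median 0.74), with Shh itself at 289 against 41 UMIs (7.65-fold, 5.50 to 10.9), Hand2 1.67-fold and Smo 1.20-fold higher, and Gli3 and Gas1 at ratios of 0.627 and 0.897. Shh lies on chromosome 5 (28456815 to 28467256).

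WNT genes stood apart on the lower side, with 3 higher and 8 lower of 18 (median -0.89): Tcf7 was 4.19-fold, Lef1 3.71-fold and Nkd1 2.16-fold lower, and Wnt5a 2.56-fold higher. Over 129_E9.5, B6_E10.5 had ratios of 0.479 for Tcf7, 0.486 for Lef1, 0.830 for Nkd1 and 3.16 for Wnt5a. FGF genes had 2 higher and 1 lower of 15 (median -0.25), while the most abundant members Il17rd, Fgfr1 and Dusp6 were 1.93-fold, 1.90-fold and 1.39-fold higher and Spred1 had a ratio of 0.794. Glycolysis genes had 2 higher and 4 lower of 18 (median -0.56), with Eno1 3.34-fold, Ldha 2.20-fold, Aldoa 1.88-fold and Pkm 1.33-fold lower. Oncofetal and imprinted genes had 1 higher and 5 lower of 15 (median -0.53), with the cell-cycle inhibitor Cdkn1c 5.49-fold and Hmga2 1.18-fold higher and Peg3 1.5-fold and Mest 1.29-fold lower. The FGF and oncofetal lists were also lower in 129_E9.5 over B6_E9.5 (medians -0.64 and -0.54). G2 and M phase genes had 1 higher and 0 lower of 17 (median 0.26), with Top2a 1.66-fold, Ube2c 1.46-fold and Cenpf 1.27-fold higher and Birc5 at a ratio of 0.909. The 4 Y-linked genes were higher (median 0.80), with Uty at 2.02-fold, Eif2s3y 1.76-fold, Kdm5d 1.72-fold and Ddx3y 1.65-fold. As this list measures the mix of embryo sexes, the libraries may differ in that mix. Sex mix and stage were not told apart in either tissue class. Haemoglobin genes, which belong to erythroid cells, had 0 higher and 5 lower of 7 (median -1.84), with Hba-x 4.23-fold, Hbb-y 4.13-fold and Hba-a1 3.57-fold lower. Lmx1b was 2.88-fold lower (2.73 to 3.03) and Tbx5, on chromosome 5 (119832668 to 119885219), 1.97-fold higher (1.91 to 2.03), while Fgf8 was at 1.38 and 2.58 CPM and Wnt7a rested on 8 and 30 UMIs.

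The remaining lists did not stand apart, with medians of -0.21 for dorsoventral patterning, 0.11 for BMP signalling, 0.07 for retinoic acid, 0.21 for limb bud transcription factors, -0.07 for keratins and junctions, -0.02 for S phase, 0.21 for stress, -0.005 for mitochondrial transcripts and -0.04 for housekeeping genes. With members of at least 100 UMIs keratins and junctions stood apart on the lower side (median -0.76, percentile 0.13). Against 129_E9.5 as the earlier library, a comparison added after the data were seen, 12 of the 12 higher named genes and 8 of the 12 lower ones were also at least 2-fold apart, the exceptions being Hmga1, Jaml, Hbb-bh1 and Usp50. Of the 3140 genes tested in both comparisons, which included 151 of the 151 higher and 50 of the 88 lower genes, 86 were higher and 18 lower against both, where independent lists would share 7.21 and 0.908 and simulated unchanged libraries 0, and the covariance of the log2 ratios was 0.230 against 0.000233 simulated from counting error alone (correlation 0.626 against 0.488). Most own clusters of mesenchyme were nearly specific to a library (clusters 1, 3 and 8 for B6_E9.5, 2, 4, 6, 7 and 9 for B6_E10.5, 0, 5 and 17 for 129_E9.5), except cluster 10 with 652, 638 and 417 cells of the 3 libraries and cluster 18 with 363, 0 and 277, so that mesenchymal subtypes were not matched across libraries. Cluster 3 was shallow and mixed, with a median of 799 UMIs per cell. Of its 3686 cells, 3436 were of B6_E9.5, and 2887 lay in the mesenchyme class and 743 in the erythroid class.

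**Figure D4:**
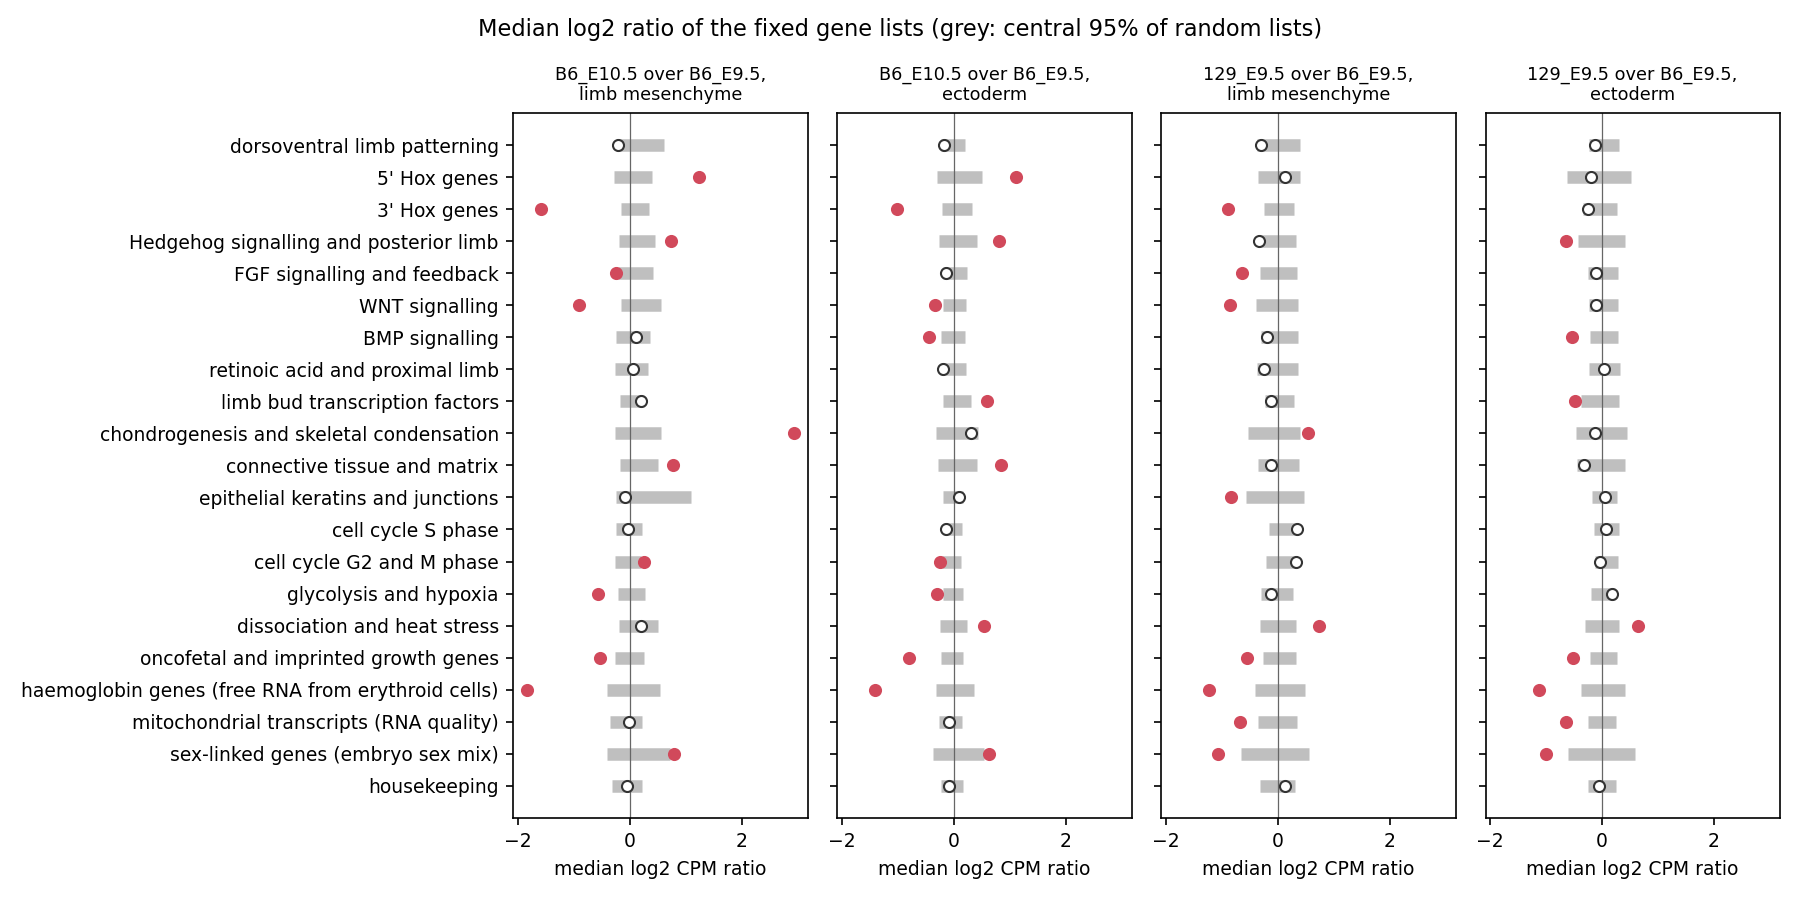
Median log2 ratio of each fixed gene list in the stage and strain comparisons, in limb mesenchyme and ectoderm, as points over grey bars that span the central 95% of 10000 random lists matched on expression. Red points lie outside that span and open circles inside it, and the sex-linked list holds the 4 Y-linked genes; in the stage comparison of mesenchyme chondrogenesis stands at 2.94 and the 3′ Hox genes at -1.57.

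In the ectoderm, the same stage comparison showed the 3′ Hox and BMP lists lower in B6_E10.5 than in B6_E9.5. Gjb2, which encodes connexin 26, was at 132 CPM against 0.931 (ratio 142, 77.0 to 298), and the basal keratin gene Krt14 was 6.49-fold higher (5.63 to 7.51). The AP-2 gene Tfap2b was 13.3-fold higher (11.4 to 15.5), the zinc-finger genes Bcl11b and Bcl11a 13.2-fold and 10.2-fold, and the chemokine gene Cxcl14 9.38-fold (8.72 to 10.1). Nfib (9.66-fold), Scube1 (9.04-fold), Wnt7b (8.89-fold), Anxa2 (7.90-fold), the galectin gene Lgals7 (7.06-fold) and Mfap4 (6.29-fold) completed the largest ratios. Hist1h2ap was 15.1-fold lower, Prtg 10.01-fold, Peg10 7.50-fold, Hmga1 7.26-fold, Hbb-bh1 5.51-fold, Lin28a 5.48-fold (4.49 to 6.73), Erh 4.64-fold, Sct 4.46-fold, the glycolytic gene Eno1 3.25-fold, Hba-x 3.25-fold, the cystine transporter gene Slc7a11 3.14-fold and Hbb-y 2.99-fold. Of 3275 genes tested, 78 were at least 2-fold higher and 47 lower, and with totals without haemoglobin, mitochondrial and ribosomal protein genes 119 were higher.

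Fgf8 was 1.90-fold higher (1.83 to 1.97), Wnt7a 1.80-fold lower (1.53 to 2.13) and En1 at a ratio of 0.888 (0.802 to 0.983), while Lmx1b was at 1.10 with an interval that included 1. The 20 3′ Hox genes had 1 higher and 10 lower (median log2 ratio -1.01), with Hoxc5 2.29-fold, Hoxb2 1.82-fold, Hoxc8 1.60-fold and Hoxc6 1.48-fold lower. BMP genes had 1 higher and 3 lower of 15 (median -0.43), with Bambi 2.57-fold, Msx2 2.46-fold, Id3 1.84-fold and Id2 1.73-fold lower. Over 129_E9.5, also of E9.5, the B6_E10.5 ratios of these genes lay nearer to 1: Bambi 0.721, Msx2 0.943, Id3 0.772 and Id2 0.849. Their stage ratios may therefore rest in part on the B6_E9.5 library. WNT genes had 4 higher and 3 lower of 17 (median -0.34), with Lef1 1.62-fold, Sp8 1.61-fold, Wnt6 1.49-fold and Wnt5a 1.26-fold lower. Connective tissue and matrix genes had 4 higher and 0 lower of 11 (median 0.84), with Fn1 1.82-fold, Tcf4 1.79-fold and Thbs1 1.37-fold higher and Col1a2 at 0.955. Hedgehog genes had 7 higher and 0 lower of 14 (median 0.81), with Ptch1 2.84-fold, Gas1 1.5-fold and Smo 1.36-fold higher and Tbx3 1.99-fold lower. Limb bud transcription factors had 6 higher and 2 lower of 19 (median 0.60), with Asb4 2.06-fold and Emx2 1.67-fold higher, Sall4 4.01-fold lower and Prrx2 at 0.830.

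Mesenchymal RNA was counted in the ectodermal sums, at a level that differed between the libraries. After the data were seen, 16 mesenchymal genes, with the 5′ Hox list and Tbx5 left out (at least 50 CPM in mesenchyme of all libraries, and in 129_E9.5 at most 10% of that in ectoderm) were taken as its measure. Their median ectodermal level was 6.15% of their mesenchymal level in B6_E9.5 and 10.4% in B6_E10.5. Hoxa9, at 2.11-fold in ectoderm, stood at 3.57% and 10.497% of its mesenchymal level, Hoxd9 (ratio 1.24, with an interval that included 1) at 3.74% and 10.9%, and Tbx5 (64 against 13 UMIs) at 1.75% and 7.63%, and for these genes a difference within the ectoderm cannot be told apart from that background. Asb4 and Prrx2, among the 16 genes, stood at 8.78% and 10.3% and at 14.96% and 10.49%. Hoxc9, 1.26-fold higher, and Hoxc10, at 163 against 5 UMIs (56.8, 23.8 to 177), had more CPM in ectoderm than in mesenchyme in both libraries. The 9 5′ Hox genes had 6 higher and 1 lower (median 1.12), but only 2 of them were over 20% of their mesenchymal level, too few for a median. Among genes over that limit, also set after the data were seen, the 7 limb bud transcription factors no longer stood apart (median -0.18, percentile 9.24), the Hedgehog and matrix lists did (0.44 and 0.69, percentiles 98.5 and 99.9), and 76 genes were at least 2-fold higher and 47 lower.

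Glycolysis genes had 0 higher and 3 lower of 18 (median -0.30), with Ldha 2.15-fold, Aldoa 1.75-fold, Pgam1 1.5-fold and Pkm 1.25-fold lower. Oncofetal and imprinted genes had 0 higher and 5 lower of 15 (median -0.80), with Mest 1.81-fold lower, Hmga2 1.56-fold higher, Cdkn1c at 0.911 and Peg3 at 0.895. G2 and M phase genes had 0 at least 2-fold apart of 17 (median -0.24), and their most abundant members Top2a and Ube2c were 1.27-fold and 1.18-fold higher, Cenpf was at 1.03 and Birc5 at 0.847. Stress genes had 3 higher and 0 lower of 15 (median 0.54), with the immediate-early gene Jund 2.05-fold higher, and Ier2, Hspa8 and Hsp90aa1 at 0.958, 0.904 and 0.598. Haemoglobin genes had 1 higher and 6 lower of 7 (median -1.41), Hba-a1 being 2.66-fold lower. The 4 Y-linked genes were higher (median 0.64), with Ddx3y at 2.09-fold, Uty 1.57-fold, Kdm5d 1.54-fold and Eif2s3y 1.41-fold. Lists that did not stand apart had medians of -0.17 for dorsoventral patterning, -0.13 for FGF, -0.20 for retinoic acid, 0.31 for chondrogenesis, 0.09 for keratins and junctions, -0.13 for S phase, -0.09 for mitochondrial transcripts and -0.09 for housekeeping genes.

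With list members of at least 100 UMIs the Hedgehog, limb bud transcription factor and stress lists no longer stood apart (percentiles 79.4, 81.5 and 96.2). Ectodermal cells of B6_E9.5 lay mostly in own cluster 16 (824 of its 842 cells) and those of B6_E10.5 in clusters 11 and 12 (702 and 314 cells). Neural crest markers had 406 UMIs in the ectoderm of B6_E9.5, 1534 in B6_E10.5 and 361 in 129_E9.5, of which Tfap2b alone had 187, 1424 and 253. Against 129_E9.5, 11 of the 12 higher named genes (not Cxcl14) and 6 of the 12 lower ones were also at least 2-fold apart. Of the 3148 genes tested in both comparisons (78 of the 78 higher and 28 of the 47 lower genes), 40 were higher and 12 lower against both, where independent lists would share 1.88 and 0.276 and simulated unchanged libraries 0, and the covariance was 0.114 against 0.00367 simulated, while the correlation of 0.512 was below the simulated 0.586. In these overlaps part of the excess may come from the library that both sides share.

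The strain comparison asked how E9.5 mesenchyme of 129S6.sv differed from that of c57bl6.J. Glo1, which encodes the methylglyoxal-detoxifying enzyme glyoxalase 1, was at 583 CPM in 129_E9.5 against 135 CPM in B6_E9.5 (4.33-fold higher, 4.25 to 4.42), and its neighbour Btbd9 was 3.74-fold higher (3.52 to 3.98). Rpgrip1, which encodes a ciliary protein of photoreceptors, was at 0.740 CPM against 398 CPM, 538-fold lower (410.3 to 721). The translation initiation factor genes Eif3j2 and Eif3j1, which are near-identical copies, were 36.4-fold higher (32 to 41.7) and 7.49-fold lower (7.06 to 7.94), and these values are uncertain because reads can be split between them. Reads of both strains were assigned to the same reference, mm10. For Rpgrip1 and the other strain ratios, in either tissue class, read assignment and expression were therefore not told apart.

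Hddc3 was 9.87-fold, the lactate dehydrogenase gene Ldhb 4.27-fold, the actin regulator Cap1 4.18-fold, Itm2a 3.35-fold, the securin gene Pttg1 3.26-fold, the squalene synthase gene Fdft1 2.87-fold, the lysosomal gene Laptm4b 2.83-fold and the haem synthesis gene Alad 2.80-fold higher. Hmga1 was 15-fold, the histone H4 gene Hist1h4i 10.3-fold, Jaml 7.38-fold, the sodium channel gene Scn2b 7.02-fold, Lamtor3 5.67-fold, Hbb-bh1 5.57-fold, the nucleoporin gene Nup98 5.38-fold, the replication gene Rpa3 5.34-fold and the histone methyltransferase gene Kmt2d 4.58-fold lower. Of 3282 genes tested 80 were at least 2-fold higher and 116 lower, or 40.8% higher. With totals that left out haemoglobin, mitochondrial and ribosomal protein genes these were 73 and 170, or 30.04% higher. Set against B6_E10.5, 9 of the 12 higher named genes (not Ldhb, Itm2a or Fdft1) and 9 of the 12 lower ones (not Hmga1, Jaml or Hbb-bh1) were also at least 2-fold apart. Among the 3119 genes tested in both comparisons (80 of the 80 higher and 80 of the 116 lower genes), 13 were higher and 28 lower against both, where independent lists would share 1.82 and 1.69 and simulated unchanged libraries 0, and the covariance was 0.169 against 0.000291 simulated (correlation 0.598 against 0.582).

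The 3′ Hox genes had 0 higher and 8 lower of 22 (median log2 ratio -0.88), with Hoxa5 2.22-fold and Hoxd8 1.69-fold lower and Hoxd4 and Hoxa7 at ratios of 0.939 and 0.905. WNT genes had 1 higher and 8 lower of 17 (median -0.85), with the WNT target Axin2 2.38-fold, Tcf7 2.01-fold, Lef1 1.80-fold and Nkd1 1.79-fold lower. FGF genes had 0 higher and 4 lower of 14 (median -0.64), while Etv4 was 1.55-fold, Dusp6 1.46-fold and Fgfr1 1.14-fold higher and Spred1 1.74-fold lower. Chondrogenesis genes had 1 higher and 1 lower of 10 (median 0.53), with Wwp2 1.74-fold and Sox9 1.48-fold higher and Col11a1 and Sox6 at 0.779 and 0.672. Stress genes had 3 higher and 0 lower of 18 (median 0.74), with the chaperone genes Hspa8 1.99-fold and Hsp90aa1 1.60-fold and the immediate-early genes Ier2 1.75-fold and Jund 1.27-fold higher. Oncofetal and imprinted genes had 0 higher and 5 lower of 15 (median -0.54), with Mest at 1.03, Hmga2 at 0.984, Peg3 at 0.921 and Igf2bp1 at 0.752. Mitochondrial transcripts had 0 higher and 4 lower of 11 (median -0.67), with mt-Nd1 1.59-fold, mt-Atp6 1.39-fold and mt-Co2 1.18-fold lower and mt-Co3 1.01-fold lower. Haemoglobin genes had 1 higher and 5 lower of 7 (median -1.22), with Hba-x 2.70-fold, Hbb-y 2.67-fold and Hba-a1 2.32-fold lower. The Y-linked genes had 0 higher and 3 lower of 4 (median -1.07), with Kdm5d 3.17-fold, Eif2s3y 2.12-fold, Ddx3y 2.09-fold and Uty 1.88-fold lower. A differing mix of embryo sexes was not told apart from strain in either tissue class.

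Keratins and junctions had 1 higher and 6 lower of 15 (median -0.82), with Tfap2a 2.58-fold higher and Cdh3, Krt8 and Krt18 at 1.13, 1.03 and 0.954 with intervals that included 1, and with cells of at least 2000 UMIs the list no longer stood apart (percentile 5.55). The other lists did not stand apart, with medians of -0.30 for dorsoventral patterning, 0.13 for 5′ Hox genes, -0.34 for Hedgehog, -0.19 for BMP, -0.24 for retinoic acid, -0.13 for limb bud transcription factors, -0.12 for connective tissue and matrix, 0.34 for S phase, 0.33 for G2 and M phase, -0.13 for glycolysis and 0.13 for housekeeping genes. S phase and G2 and M phase genes lay just inside the limit (percentiles 97.25 and 97.19) and outside it with members of at least 100 UMIs (97.98 and 97.7), as did S phase with TMM factors (97.6) and G2 and M phase with cells of at least 2000 UMIs (97.8). Lmx1b was 1.43-fold lower (1.37 to 1.49), Hoxd13 1.53-fold higher (1.38 to 1.70) and Tbx5 1.09-fold higher (1.06 to 1.13). En1 was at a ratio of 0.928 with an interval that included 1, Fgf8 at 0.474, and Shh, Hoxa13 and Wnt7a rested on 23 against 41, 0 against 5 and 5 against 30 UMIs.

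In the ectoderm, 129_E9.5 had more of the basal keratin Krt5 (3.49-fold, 3.06 to 4.0) and of Cxcl14 (6.07-fold, 5.62 to 6.56), and less of Spry2, a feedback inhibitor of FGF signalling (6.65-fold lower, 5.67 to 7.83). Gpx6, of the glutathione peroxidase family, was at 76.9 CPM against 3.91 (19.7-fold higher, 14.3 to 27.6), and the WNT potentiator Rspo2 was 3.16-fold higher. En1 was level between the strains at this depth (ratio 0.964, 0.874 to 1.06), Fgf8 was 1.41-fold higher (1.35 to 1.46) and Wnt7a was at 1.17 (1.03 to 1.33), a direction that did not hold in thinned cells (log2 ratio -0.17). Eif3j2 (28-fold), Hddc3 (6.76-fold), Cap1 (4.45-fold), Glo1 (4.05-fold), Rnf121 (3.49-fold), the small heat shock gene Hspb1 (3.46-fold) and Pttg1 (3.26-fold) were higher. Lower were Rpgrip1 (81.2-fold, 52.5 to 133), Hist1h4i (12.1-fold), Hmga1 (9.12-fold), Eif3j1 (6.02-fold), Lamtor3 (5.53-fold), Rpa3 (5.48-fold), Hist1h2ap (4.71-fold), Kmt2d (4.32-fold), Hbb-bh1 (4.30-fold) and the spliceosome gene Snrpf (4.17-fold). Of 3330 genes tested 52 were at least 2-fold higher and 86 lower. Thinned cells gave 87 higher, and totals without haemoglobin, mitochondrial and ribosomal protein genes 131 lower.

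BMP genes had 0 higher and 3 lower of 14 (median log2 ratio -0.53), with Bambi 1.85-fold, Id2 1.47-fold, Id3 1.42-fold and Msx1 1.37-fold lower. Hedgehog genes had 0 higher and 3 lower of 9 (median -0.64), with Gli3 1.58-fold and Tbx3 1.55-fold lower, Smo 1.15-fold higher and Gas1 at 0.957. Limb bud transcription factors had 1 higher and 3 lower of 17 (median -0.48), with Emx2 2.09-fold higher, Asb4 1.53-fold lower, and Prrx2 and Sall4 at 0.918 and 0.829. Stress genes had 4 higher and 0 lower of 15 (median 0.64), with Jund 1.90-fold, Ier2 1.47-fold and Hsp90aa1 1.19-fold higher and Hspa8 at 1.03. Oncofetal and imprinted genes had 0 higher and 5 lower of 15 (median -0.52), with Mest 1.43-fold lower and Cdkn1c 1.46-fold, Hmga2 1.26-fold and Peg3 1.14-fold higher. Mitochondrial transcripts had 0 higher and 2 lower of 11 (median -0.64), with mt-Nd1 1.57-fold and mt-Atp6 1.54-fold lower. Haemoglobin genes had 0 higher and 6 lower of 7 (median -1.12) and Y-linked genes 0 higher and 2 lower of 4 (median -0.99), with Kdm5d 3.29-fold, Eif2s3y 2.15-fold, Uty 1.85-fold and Ddx3y 1.58-fold lower. Lists that did not stand apart had medians of -0.13 for dorsoventral patterning, -0.19 for 5′ Hox and -0.25 for 3′ Hox genes, -0.11 for FGF, -0.10 for WNT, 0.04 for retinoic acid, -0.11 for chondrogenesis, -0.31 for connective tissue and matrix, 0.05 for keratins and junctions, 0.07 for S phase, -0.03 for G2 and M phase, 0.19 for glycolysis and -0.04 for housekeeping genes. Mesenchymal RNA in the ectodermal sums, measured after the data were seen by 8 mesenchymal genes at most 10% as high in the ectoderm of B6_E10.5, was at a median of 4.64% of its mesenchymal level in B6_E9.5 and 2.93% in 129_E9.5. Asb4 and Prrx2 stood at 8.78% and 14.96% of their mesenchymal levels in B6_E9.5 and at 3.90% and 9.58% in 129_E9.5. Among genes over 20% the Hedgehog and limb bud transcription factor lists, with 8 and 6 members, still stood apart (medians -0.47 and -0.67, percentiles 0.940 and 0.310). With members of at least 100 UMIs the Hedgehog list did not stand apart (percentile 5.13), and keratins and junctions did on the higher side (median 0.32, percentile 99.3). Ectodermal cells of B6_E9.5 lay mostly in own cluster 16 (824 cells of that library), and those of 129_E9.5 in clusters 11 and 12 (623 and 632 cells). Set against B6_E10.5, 8 of the 12 higher named genes (not Cxcl14, Krt5, Hspb1 or Rspo2) and 8 of the 12 lower ones (not Hmga1, Rpa3, Hist1h2ap or Hbb-bh1) were also at least 2-fold apart. Among the 3203 genes tested in both comparisons (52 of the 52 higher and 63 of the 86 lower genes), 17 were higher and 18 lower against both, where independent lists would share 0.909 and 0.688 and simulated unchanged libraries 0, and the covariance was 0.155 against 0.00341 simulated (correlation 0.690 against 0.575). As in mesenchyme, both sides share 129_E9.5 and the simulation held counting error only, so strain and library are not separated.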

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

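No test was run on the results of this part, and none of the differences named here was tested.

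Cyp26b1, which encodes an enzyme that degrades retinoic acid, went opposite ways with stage in the tissue classes: its log2 ratio of B6_E10.5 over B6_E9.5 was 4.19 in limb mesenchyme and -1.31 in ectoderm. The difference between classes was not tested, since it rests on 1 library per stage.

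En1 and Fgf8 were counted in the same ectodermal cells more often than independent counts would be in B6_E10.5, with an odds ratio of 1.69, and less often in 129_E9.5, with an odds ratio of 0.679. In B6_E9.5 the odds ratio was 0.907 with an interval that included 1, but in thinned cells it was 0.524 (0.339 to 0.794). Thinned cells gave 1.86 (1.20 to 2.84) in B6_E10.5 and 0.598 (0.415 to 0.852) in 129_E9.5. The differences between these libraries were not tested.

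Markers of neurons and neural tube stood at 838 CPM in the muscle progenitor class of 129_E9.5, against 46.9 CPM in B6_E9.5 and 51.2 CPM in B6_E10.5, with Tubb3 at 484 CPM, Stmn2 at 206 CPM and Elavl3 at 54.5 CPM. Neuron-like own cluster 25 held 71 cells, 70 of them of 129_E9.5, and 58 of its cells lay in the muscle progenitor class. Markers of macrophages and other myeloid cells stood at 1800.1 CPM in the endothelium and myeloid class of B6_E10.5, against 44.5 CPM in B6_E9.5 and 31.4 CPM in 129_E9.5. These classes are outside the stage and strain comparisons, and the differences were not tested.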

How the results depend on the processing

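The restriction to cells of at least 2000 UMIs and 129_E9.5 as the earlier library were chosen only after the data were seen, as were the removal of the 8% of cells of highest doublet score and the limit of 20% of the mesenchymal level in ectoderm. No paired analysis was possible because the stage and strain comparisons have 1 library per group. The planned comparisons of Maenli were not run. Of the named gene ratios, 1935 values under an alternative stayed within the counting interval, 362 moved beyond it and 7 changed sign where the counting interval had excluded a ratio of 1. The values that stayed include 288 without the CPM filter, which cannot change a ratio. They also include 288 with Scrublet calls removed, which took out almost no cells. In thinned cells 152 stayed, 133 moved and 3 changed sign. Sign changes of values that did not stand apart, or whose interval included 1, are not in these counts of sign changes. Of the gene list medians, 280 stayed on their side of the percentile limits, 11 did not and 1 of a list that stood apart changed sign (limb bud transcription factors, stage, ectoderm: -0.18 among genes over 20% of their mesenchymal level, with 7 members left of 19). The 5′ Hox list had too few members over that limit for a value. For the named genes of the En1 test, 251 values kept their direction and their side of the threshold, 65 no longer passed and 3 newly passed. Few UMIs limit some named genes: in ectoderm Hoxd13 rested on 11 and 5 UMIs, and Shh and Hoxa13 on fewer.

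The counted changes of sign on the log2 scale, whose cause was not tested, were those of Mest (-0.014 with totals without haemoglobin, mitochondrial and ribosomal protein genes, strain, mesenchyme), mt-Co3 (0.093 with cells of at most 5% mitochondrial UMIs and at least 2000 genes, strain, mesenchyme), Ube2c and Hoxd13 (-0.13 and -0.63 in thinned cells, stage, ectoderm), Hspa8 (-0.00027 with TMM factors and -0.080 with the same strict cells, strain, ectoderm) and Wnt7a (-0.17 in thinned cells, strain, ectoderm).

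Without the CPM filter more genes were tested, and 1980.0 genes were 2-fold higher and 761 lower for stage in mesenchyme, 703 and 1052 for strain in mesenchyme, 676 and 391 for stage in ectoderm and 383 and 604 for strain in ectoderm. Totals without haemoglobin, mitochondrial and ribosomal protein genes lowered the CPM bar and gave 119 higher for stage and 131 lower for strain in ectoderm, and thinning gave 87 higher for strain in ectoderm.

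Shares of cells moved with the choice of cells; the cause was not tested. With the strict cells, ectoderm was 9.75% of B6_E9.5, 5.81% of B6_E10.5 and 6.67% of 129_E9.5, muscle 2.85% of B6_E9.5 and 5.85% of 129_E9.5, and erythroid cells 1.61%, 1.91% and 2.93% of the 3 libraries, so that the order of the E9.5 libraries turned for ectoderm and erythroid cells. With cells of at least 2000 UMIs, ectoderm, muscle and erythroid cells were 10.03%, 3.04% and 1.78% of B6_E9.5, and muscle 8.62% of B6_E10.5. In the own clustering muscle (with somite-like cells) was 1.91% of B6_E9.5 and 4.79% of 129_E9.5, and erythroid cells 1.16% of B6_E9.5. Of non-erythroid cells, ectoderm was 8.53% in B6_E9.5 and 10.8% in 129_E9.5.

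En1 in ectoderm was found, after thinning, in 17.9% of cells of B6_E9.5 (114 CPM), 13.5% of B6_E10.5 and 15.8% of 129_E9.5, and in the strict cells in 44.3% (98.8 CPM), 39.4% and 32.5%. Thinned odds ratios with En1 were 0.524 for Fgf8 in B6_E9.5, and 0 for both Wnt7a and Lmx1b in B6_E10.5, where no cell was positive for both.

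For the En1 test, DESeq2 gave 22 genes higher and 25 lower, no filter 157 and 193, thinned cells 6 and 4 (with fewer UMIs and fewer En1-positive cells, whose parts were not separated), and En1-positive Wnt7a-negative against Wnt7a-positive En1-negative cells 312 and 251. Without the library block edgeR gave 0 and 0, with 138 genes at an unadjusted p under 0.05, since differences between the libraries then entered the spread. Leaving out each library in turn gave 8 to 243 higher and 26 to 246 lower.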

Other observations

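Of the tests in this part, those of mesenchyme markers in low-UMI erythroid cells, of haemoglobin in 129_E9.5, of summed Eif3j1 and Eif3j2, of the sign of the strain ratio and of other splits were chosen only after the result was seen.

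The muscle class differed in which myogenic genes were counted; these genes were chosen after their values were seen. Myf5, Myod1 and Myog, regulators of commitment and differentiation in muscle, had UMIs in 718, 282 and 137 of the 1498 muscle class cells of B6_E10.5 (47.9%, 18.8% and 9.15%), at 123, 55.2 and 56.5 CPM. In both E9.5 libraries they had 0 UMIs in the muscle class, over 285 cells in B6_E9.5 and 647 in 129_E9.5. Pax3, which marks migrating progenitors, was at 439 CPM in B6_E9.5, 297 in B6_E10.5 and 431 in 129_E9.5, and Lbx1 at 498, 202 and 424 CPM. Kdr, an endothelial receptor gene, was counted in 61.4% of the muscle class cells of B6_E9.5, 0.401% of those of B6_E10.5 and 32.6% of those of 129_E9.5 (median depths 10989, 7695.5 and 7550 UMIs). As a background level, 1.70%, 0.209% and 0.347% of limb mesenchyme cells had a Kdr UMI at 8067, 5422 and 7463 UMIs. The fixed endothelium markers were at 236, 48.3 and 177 CPM in the same muscle classes, of which Kdr made up 159, 0.502 and 74.2 CPM. The own clustering put the B6_E10.5 cells in clusters 13 and 21, and those of 129_E9.5 and B6_E9.5 in clusters 19 and 22, which met a share of 0.714 of the somite markers and 0.50 and 0.625 of the muscle markers. In the muscle class of B6_E9.5 and 129_E9.5, muscle markers were at 1143 and 1057 CPM and somite markers at 903 and 557 CPM.

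Smaller own clusters held different numbers of cells of each library. Macrophage-like cluster 23 held 11, 190 and 11 cells of B6_E9.5, B6_E10.5 and 129_E9.5, and the complement gene C1qb was counted in 110 of the 707 endothelial class cells of B6_E10.5 (15.6%) and in 0 in both other libraries. Pf4, a platelet factor gene, was at 165, 1068 and 249 CPM in that class. Neural-crest-like cluster 24 held 1, 72 and 53 cells and neuron-like cluster 25 held 0, 1 and 70. Of cluster 24, 123 of 126 cells lay in the endothelium and myeloid class, and of cluster 25, 58 of 71 lay in the muscle class. Mesenchyme cluster 18, which also carried mesothelium and flank markers, held 363 cells of B6_E9.5, 0 of B6_E10.5 and 277 of 129_E9.5. A cluster mostly of 1 library can be that library and not a type.

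Glo1 lies on chromosome 17 of mm10 (30584936 to 30626871) between Btbd9 (30215524 to 30576488) and Dnah8 (30624354 to 30877365), genes looked at after their values were seen. In mesenchyme, 129_E9.5 over B6_E9.5 and over B6_E10.5 had CPM ratios of 4.33 and 3.55 for Glo1, 3.74 and 2.09 for Btbd9, and 4.06 and 2.08 for Dnah8, which was at 0.413 CPM in 129_E9.5. Of the other 15 genes with at least 20 UMIs within 1 Mb on each side, Dnah8 was the single gene at least 2-fold higher than in both other libraries. No explanation was tested.

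The erythroid class of B6_E9.5 held few haemoglobin UMIs. Of its 951 cells 794 had under 2000 UMIs (median 679.5), with haemoglobin at a median of 3.34% of UMIs. The median haemoglobin share of erythroid cells in 129_E9.5, also at E9.5, was 100.7% of that in B6_E10.5. A low share was therefore not a feature of every E9.5 library. This does not decide on stage as the cause, since 129_E9.5 also differs from B6_E9.5 in strain and library. A candidate explanation is that the low-UMI droplets hold RNA of other cells: limb mesenchyme markers in them reached 80.1% of their CPM in low-UMI mesenchyme cells of the same library. Whether the B6_E9.5 erythroid cells as a whole held less haemoglobin RNA stayed open, with 73.8% of the B6_E10.5 median in the 157 cells of at least 2000 UMIs.

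Eif3j1 and Eif3j2 differed between the strains in opposite directions in both tissue classes. Their summed CPM had a strain ratio of 0.773 in mesenchyme (95% interval 0.751 to 0.795) and 0.780 in ectoderm (0.70 to 0.868). Reads shared between the near-identical copies, assigned by strain variants against the reference, may therefore account for most of the opposite change. The remaining difference of the sum was not tested, and a difference in expression between the strains stays open.

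Stage and strain genes overlapped in mesenchyme, with 20 genes higher and 38 lower in both comparisons among the 3097 tested in both (70 of the 151 higher and 88 of the 88 lower stage genes), where independent lists would share 1.31 and 3.30 and simulated unchanged libraries 0. The covariance of the log2 ratios was 0.170 against 0.000211 simulated from counting error alone (correlation 0.566 against 0.455), and both comparisons share B6_E9.5, so part of the excess may come from that library. Embryos of 129_E9.5 further along in development could give the same sign in both, seen for 87.9% of the 2-fold stage genes, but the shared library gives this too and the test does not decide. Of the 2-fold stage genes 48.1% were also 2-fold apart between B6_E10.5 and 129_E9.5, and of the 196 strain genes 43.9% had a 129_E9.5 level within 1.5-fold of B6_E10.5, both between the bounds set for a B6_E9.5 library that stands apart. Stage, strain and library cannot be told apart here, because each group is 1 library.

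For the En1 test, the 10 splits of the 6 sums are too few for a share under 0.05: 1 split, the real one, reached 152 genes, and the highest of the others reached 1.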
